A study of Homo sapiens with 6 samples.

How the data were processed

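RNA of M14 cells, an established human melanoma line, was sequenced from conventional adherent culture (2D, 3 libraries) and from non-adherent culture as melanospheres, which are floating multicellular spheres (3D, 3 libraries). Group and replicate number of each library were taken from the sample titles. Per the labels' protocols, RNA was extracted with a column kit, poly(A) libraries were made with the Illumina TruSeq RNA kit (v2) and sequencing was run on an Illumina NovaSeq. This kit does not mark the strand, so reads from a gene and from an overlapping antisense gene cannot be told apart. Per the submitters' processing notes, HISAT2, featureCounts 1.5.0 and DESeq2 were used with GRCh38/hg38. The versions of HISAT2 and DESeq2 and the annotation release are not given in the sources used here. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

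The deposited values are a signal per gene that the authors made by dividing read counts by 1 size factor per library, as the file's name and its values show. Every library's values were whole multiples of a single step, and 100% of them came out as whole reads within a tolerance of 0.01 of a read. Factors recomputed from these reads by the median of ratios differed from the deposited scaling by at most 6.1e-11. The recovered totals ran from 16567763 to 19954987 reads per library, with 20841 to 21772 genes detected in 2D and 22458 to 23572 in 3D. The table held 26748 Ensembl genes, none of them at 0 in every library, and 6 empty columns, which were not used. Symbols were found for 26506 genes in a name table, and 26702 genes were in GENCODE 29 (GRCh38), from which biotypes and coordinates were taken. POU5F1, SOX2 and NANOG were not analysed here.

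Genes with a mean of at least 10 normalised counts over the 6 libraries were tested, 15598 in all. The test was limma 3.58.1 (R 4.3.3) on log2(value + 1), with lmFit and eBayes with a trend, culture as the only term, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on this log2(value + 1) scale, which understates the change of low genes. Where a culture had no reads of a gene, the fold is given as a lower bound against 3 reads summed over that culture. Where it had 1 to 3 reads, the ratio of summed reads is given with an exact 95% binomial interval. Such intervals and floors cover counting error only, since PCR copies are not independent molecules. Values are mean ± SD of normalised counts over 3 libraries per culture unless stated.

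Before the data were examined, 49 gene lists, the rule for naming genes, the tests and the alternatives were fixed. Of the lists, 48 had at least 5 tested genes and were tested with limma's camera, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera asks whether the genes of a list moved more than other genes. Members past the gene threshold were counted with p adjusted over all genes tested and adjusted over the list alone. Camera with an estimated correlation and fry were run as alternatives. A call lost with an estimated correlation does not by itself show that members of a list moved together. Fry asks whether a list's genes moved on balance in 1 direction, without comparing them with other genes. The rule named the 10 protein-coding genes with the largest change in each direction (adjusted p under 0.05, no overlap between the cultures, mean of at least 100 in the higher culture), the 5 genes with the smallest adjusted p in each direction at that mean, up to 4 members in the direction and 2 against it of each list past the set test, up to 3 members of other lists described, and 14 markers of putative melanoma stem cells or of melanoma state: CD44, PROM1, ABCB5, ALDH1A1, ALDH1A3, NES, NGFR, SOX2, SOX10, POU5F1, NANOG, MITF, AXL and MKI67. Genes named outside this rule (TERT, CD24, ALCAM, MCAM and those in the closing section) were chosen after their values were seen.

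Other alternatives were pseudocounts of 0.1 and 10, no filter, a mean of at least 50, rescaling by TMM, by the median of ratios or to equal library totals, the replicate number as a block, robust eBayes, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 tests on the recovered whole reads, stricter thresholds, and leaving out each library in turn. The edgeR test called 3657 genes. All 10 splits of the 6 libraries into 3 and 3 were refitted. For each named gene, the share of its 75-base windows that also occur in transcripts of another GENCODE 29 gene was computed with Python 3.11.15 and pandas 2.3.3. Genes with more than about 20% of such windows are reported as uncertain. The workflow was tested on simulated counts for the 15598 genes, with 200 of them changed. It recovered 15% of changes of 1 and 71% of changes of 2 on the log2 scale and called 5 unchanged genes. A simulated list of 20 changed genes was called and no unchanged list was. Genes were simulated independently of each other, so this does not show how the list test behaves where genes of a list move together. Figures were drawn with matplotlib 3.10.9.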

Results

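The series compared the M14 melanoma line grown adherent in 2D with the same line grown as non-adherent 3D melanospheres, to characterise putative cancer stem cell populations in the spheres. Each culture had 3 RNA-seq libraries. Depth was similar throughout, from 16567763 to 19954987 reads assigned to genes per library. The libraries were less alike within 2D than within 3D. Across genes, log2 values correlated at r = 0.984 between 2D replicates 1 and 2, but at 0.943 to 0.945 between these and 2D replicate 3. In 3D, replicates 1 and 3 correlated at 0.987, and replicate 2 with them at 0.966 to 0.967. On the first principal component, which held 68.4% of the variance, 2D replicate 3 lay at -24.7, between the other 2D libraries (-94.7 and -84.4) and the 3D libraries (59.3 to 73.9). No pair of libraries agreed within sampling noise (a mean chi-square of at least 9.65 per gene), so none was taken for a repeat deposit of another; this does not show that they came from separate cultures. Genes are not independent replicates, and these correlations describe the libraries only.

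**Figure D1:**
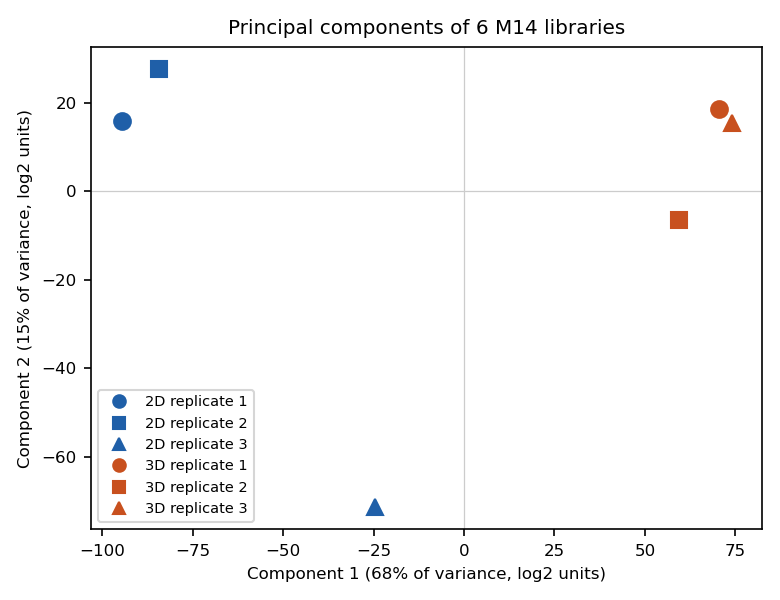
Principal components 1 and 2 of the 6 libraries, from log2(normalised count + 1) of the tested genes, both axes in log2 units and each point a library. The 3D libraries sit together at 59.3 to 73.9 on component 1, and 2D replicate 3 sits at -24.7, apart from the other 2D libraries.

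The sphere culture differed from the adherent culture in a large part of the transcriptome. Of 15598 genes tested, 1950 were higher and 1816 lower in 3D (limma, Benjamini-Hochberg adjusted p under 0.05), 3766 in all. Of the 12713 protein-coding genes tested 1394 were higher and 1715 lower, and of the other 2885 genes 556 were higher and 101 lower. With a change of at least 1 on the log2 scale, 1624 were higher and 1003 lower. The count depended on the libraries: it was 1549 without 2D replicate 1, 1793 without 2D replicate 2, 7111 without 2D replicate 3, 1307 without 3D replicate 1 and 1190 without 3D replicate 3, and 9041 with 2D replicate 3 and 3D replicate 2 both left out, a fit added after the data were seen. With libraries rescaled to equal totals, 2391 genes were higher and 1253 lower, as the median log2 change of all tested genes moved from -0.02 to 0.11.

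Of the protein-coding genes with the largest rise in 3D, MYH15 (ENSG00000144821, chromosome 3, 108380369 to 108529322, GRCh38), a myosin heavy chain, had no reads in 2D and 133 ± 134 normalised counts in 3D, at least 131-fold higher. That value rested on 3D replicate 2, with 288 against 54.7 and 55.7 in the other 3D libraries: the bound was 54.5 without it and up to 173 over the 6 fits with a library left out. MMP1, the interstitial collagenase, had 3 reads in 2D and 602 in 3D, a ratio of 193 (interval 65.7 to 938), which was 123 (41.7 to 602) without 3D replicate 2 and 388 (69.4 to 15367) without 2D replicate 3. ITGA10 (ENSG00000143127, chromosome 1, 145891208 to 145910189), a collagen-binding integrin subunit, rose from 12.1 ± 8.24 to 776 ± 184, a log2 change of 6.10 (SE 0.51, adjusted p = 0.00044; 5.50 without 2D replicate 1). PECAM1, an adhesion molecule of endothelial cells and platelets, rose from 3.08 ± 5.34 to 117 ± 32.6, with all 2D reads in 2D replicate 3. LAPTM5 had 2 reads in 2D and 427 in 3D, a ratio of 205 (interval 56.5 to 1700.02) that was 110 (29.9 to 915) without 3D replicate 2. RANBP3L, MTUS2, MYBPC2 and GPR141 had log2 changes of 5.38 to 6.20 (4.84 to 6.83 with a library left out). AKR1C2, with 3 reads in 2D and a ratio of 165 (interval 56.04 to 801; 83.9, 28.2 to 411, without 3D replicate 2), is uncertain, since 41.3% of its sequence windows also occur in another gene, chiefly AKR1C1. By smallest adjusted p, UNC13A, which primes synaptic vesicles, rose from 87.6 ± 16.2 to 1716 ± 249 (log2 4.28, SE 0.22, adjusted p = 7.9e-05), SEMA3A, a secreted guidance cue, from 11.2 ± 3.88 to 325 ± 53.03, and STRA6, the retinol transporter, from 83.8 ± 9.06 to 582 ± 31.5. LINC02395 had no reads in 2D and was at least 98.4-fold higher in 3D (63.5 to 118 with a library left out). GAS6-AS1 rose by 3.24 on the log2 scale; 1.93% of its windows occur in transcripts of GAS6, and its reads cannot be told apart from unspliced RNA of GAS6, which lies on the other strand.

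The largest fall was that of PLEKHG4B (ENSG00000153404, chromosome 5, 92151 to 189972), from 3201 ± 643 in 2D to 3.95 ± 2.14 in 3D (log2 -9.41, SE 0.36, adjusted p = 2.4e-05). ANO2, a calcium-activated chloride channel, fell from 910.2 ± 408 to 1.69 ± 2.17, and CRB1, a cell polarity protein, from 674 ± 342 to 5.71 ± 4.696. PTPRQ, a receptor-type phosphatase, had 124 ± 81.9 in 2D and no reads in 3D, at least 127-fold lower (172 without 2D replicate 3, which had 32.9, and 82.3 to 114 without another library). The list went on with the retinaldehyde reductase DHRS3, the sodium leak channel NALCN, the metalloreductase STEAP4, the pro-apoptotic HRK, the iron-siderophore binding LCN2 and the potassium channel KCNH5, with log2 changes of -6.21 to -5.68 (-7.53 to -4.86 with a library left out). The call of LCN2 was lost without 2D replicate 1, 2D replicate 2, 3D replicate 1 or 3D replicate 2 (adjusted p of 0.00013 to 0.073 over the 6 fits with a library left out). By smallest adjusted p, OLR1, a receptor for oxidised LDL, fell from 4523 ± 779 to 151 ± 33.6, the zinc finger gene ZXDB from 7366 ± 666 to 861 ± 68.1, the cancer-testis antigen XAGE2 from 1013 ± 108 to 42.4 ± 11.2, and the transcription factor MECOM from 2999.8 ± 137 to 449.6 ± 36.6.

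Markers used for putative melanoma stem cells did not move together in the spheres. Of 18 tested genes of that list, CXCR4 and CD44 rose and 5 fell, namely PROM1, EPCAM, CD24, ALCAM and MCAM, and the counts adjusted over the list alone were also 2 and 5. The list did not pass the set test (camera, adjusted p = 0.87; its median log2 change of 0.09 and the direction of the test differed in sign). CXCR4, a chemokine receptor, rose from 729 ± 610.4 to 5548 ± 1309 (log2 3.21, SE 0.48, adjusted p = 0.0037; 3.85 without 2D replicate 3). CD44 (ENSG00000026508, chromosome 11, 35138870 to 35232402), the hyaluronan receptor, rose from 2498 ± 1442 to 6398 ± 720.1 (log2 1.49, SE 0.34, adjusted p = 0.017). PROM1 (ENSG00000007062), which encodes CD133, had 24.6 ± 16.2 in 2D and no reads in 3D, at least 25.3-fold lower (adjusted p = 0.0069; 16.5 to 34.6 with a library left out). NES did not pass (1335 ± 1636 against 2386 ± 571, adjusted p = 0.14): 2D replicate 3 had 3222, and without it the log2 change was 2.60 (adjusted p = 0.00012, the lowest of the 6 fits, in which it reached 0.41). NGFR (121 ± 99.3 against 139.7 ± 53.2) and ALDH1A3 (100.2 ± 20.8 against 115 ± 38.2, 34.0% of windows shared with another gene) did not pass, with adjusted p of 0.60 and 0.76. ABCB5 and ALDH1A1 were too low to test, at means under 5 in both cultures. Without 2D replicate 1, 2D replicate 2, 3D replicate 1 or 3D replicate 3 the call of CD44 was lost (adjusted p of 4.9e-05 to 0.072 over the 6 fits), and so were those of CD24, ALCAM and MCAM, leaving 1 gene of the list higher and 2 lower. Without 2D replicate 3, 4 were higher and 6 lower.

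**Figure D2:**
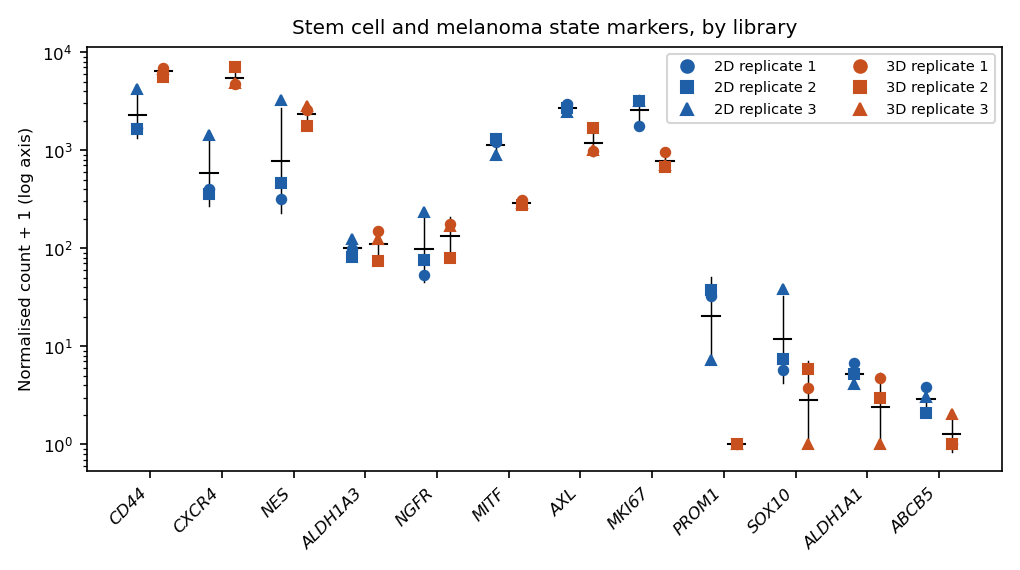
Normalised count + 1, on a log axis, of 12 markers of putative stem cells or melanoma state, with each point a library and black lines the mean and SD of the log2 values of 3 libraries. CD44 and CXCR4 lie higher in all 3D libraries, MITF, AXL and MKI67 lie lower, and PROM1 has no reads in 3D.

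Of the pluripotency factors, 7 were tested. SALL4 rose from 954 ± 139.7 to 2098 ± 76.6 and TERT, the telomerase catalytic subunit, also rose. KLF4 fell from 610.4 ± 141 to 246 ± 103 and BMI1 from 457 ± 69.6 to 194 ± 87.8, although 27.6% of the windows of BMI1 are shared with another gene. The list did not pass (camera, adjusted p = 0.77), and adjusted over the list alone the counts were again 2 higher and 2 lower. Only SALL4 kept its rise without 2D replicate 1, 2D replicate 2, 3D replicate 1 or 3D replicate 3, where 1 of the 7 was higher. KLF4 lost its call without 2D replicate 1, 3D replicate 1 or 3D replicate 3, and BMI1 without any of these or 2D replicate 2, with adjusted p of up to 0.087.

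Genes of mitosis fell in the spheres. Of 33 genes of the G2 and M phase list, 28 fell and none rose (31 fell adjusted over the list alone), with a median log2 change of -1.41 (camera, adjusted p = 6.0e-17). That call was lost with an estimated correlation (adjusted p = 0.52). NDC80, a kinetochore protein, fell from 685 ± 76.9 to 115 ± 7.703, UBE2C, an E2 enzyme of the anaphase-promoting complex, from 2806 ± 181 to 455 ± 107, the mitotic kinesin KIF11 from 2657 ± 265 to 801 ± 56.8, and CKAP2L from 650.4 ± 40.4 to 119.9 ± 29.3. The proliferation marker MKI67 fell from 2686 ± 817 to 775 ± 156 (log2 -1.76, SE 0.27, adjusted p = 0.0039). Genes of S phase did not pass as a list (camera, adjusted p = 0.24): 1 of 32 rose and 4 fell, also adjusted over the list alone. RRM1, a ribonucleotide reductase subunit, fell from 8589 ± 295 to 3934 ± 424 and the exonuclease EXO1 from 1070.0 ± 346 to 315 ± 67.5. Among 20 cell cycle inhibitors and quiescence genes, 2 rose and 6 fell (3 and 7 adjusted over the list alone; camera, adjusted p = 0.58), with CDKN1B, which encodes the inhibitor p27, falling from 3295 ± 313 to 1609 ± 119.5. Of 16 replication-dependent histone genes, which yield mostly non-polyadenylated transcripts, 2 rose and 2 fell, also adjusted over the list alone (camera, adjusted p = 0.33). Without 2D replicate 3, 3 S phase genes were higher and 6 lower, 6 of the inhibitors were higher and 9 lower, and 4 histone genes were higher and 2 lower. Without 2D replicate 1 only 3 inhibitors fell, and 4 fell without 2D replicate 2 or 3D replicate 1. Of the histone genes, 0 were higher and 0 lower without 2D replicate 1 or 3D replicate 1. Without 2D replicate 2, 1 was higher and 0 lower, and without 3D replicate 2, 0 were higher and 2 lower.

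Genes of cholesterol synthesis rose, although the list did not pass fry (adjusted p = 0.068). Of 25 genes, 21 rose and none fell, in all genes and adjusted over the list alone, with a median log2 change of 1.84 (camera, adjusted p = 3.5e-10; adjusted p = 0.97 with an estimated correlation). INSIG1, a sterol sensor, rose from 734 ± 531 to 5918 ± 1035 (log2 3.22, SE 0.42, adjusted p = 0.0020). The pathway enzymes MSMO1, MVD and FDPS rose from 549.6 ± 331 to 3096 ± 660.2, from 545 ± 385 to 2871 ± 358 and from 1319 ± 688 to 4781 ± 179.9. The mean level of the list in 2D replicate 3 was -0.04 on a log2 scale centred over the libraries, between the other 2D libraries (-1.19 and -1.35) and the 3D libraries (0.81 to 0.93). Fatty acid synthesis genes did not pass camera as a list (adjusted p = 0.14) but passed fry (adjusted p = 0.026), with 7 of 14 higher and 2 lower (7 and 3 adjusted over the list alone). Members that rose numbered 4 without 3D replicate 1 and 3 without 3D replicate 3, with 1 lower in each. ACSL1 and ACSS2, which activate fatty acids and acetate, rose from 466 ± 83.7 to 2426 ± 334 and from 839 ± 169.8 to 4559 ± 1036, and the elongase ELOVL6 from 509 ± 116 to 1672 ± 48.2. Among 8 cholesterol efflux genes and targets of the sterol receptor LXR, 3 rose and 1 fell, also adjusted over the list alone (camera, adjusted p = 0.63), and 1 rose without 2D replicate 2, 3D replicate 1 or 3D replicate 3. APOC1 rose from 233 ± 35.7 to 637 ± 62.2, with 30.9% of its windows shared with another gene.

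**Figure D3:**
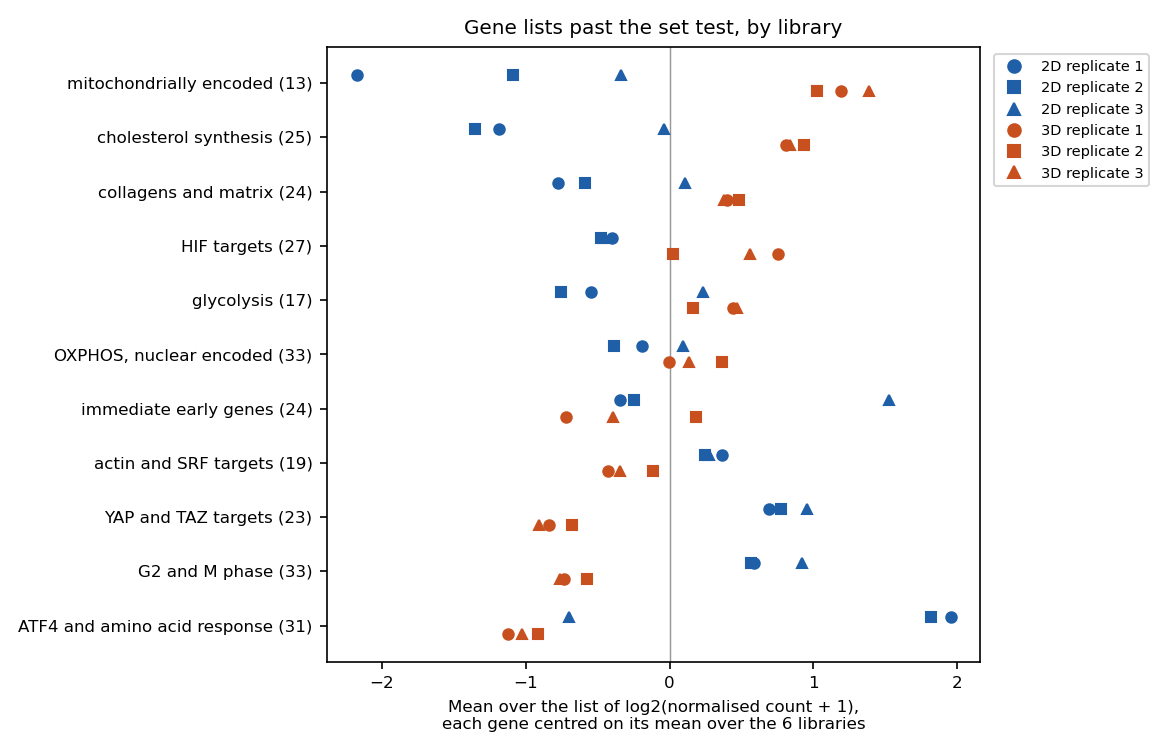
Level of the 11 gene lists past the set test in each library, as the mean over the list of log2(normalised count + 1) with each gene centred on its mean over the 6 libraries (horizontal axis, log2 units), with the number of tested genes in brackets. 2D replicate 3 lies near the 3D libraries for the ATF4 list (-0.70 against -1.12 to -0.92) and far above all others for immediate early genes (1.52).

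Transcripts encoded by the mitochondrial genome rose: 12 of 13 genes (13 adjusted over the list alone), with a median log2 change of 2.52 (camera, adjusted p = 3.4e-08; adjusted p = 0.97 with an estimated correlation). This list did not pass fry (adjusted p = 0.064). MT-CYB, a subunit of complex III, rose from 6256 ± 2908 to 32996 ± 5589 and MT-CO3, of complex IV, from 21179 ± 9385 to 106145 ± 14686. MT-ND1 and MT-ND2, of complex I, rose by 2.24 and 1.82 on the log2 scale, the latter with 34.4% of its windows shared with other genes. Genes of the mitochondrial genome, ribosomal RNAs included, took 1.011% ± 0.482 (SD, n = 3) of the reads in 2D and 5.04% ± 0.743 (SD, n = 3) in 3D, with 2D libraries at 0.528%, 1.013% and 1.49%. Nuclear genes of oxidative phosphorylation passed the set test with a median of 0.29 (camera, adjusted p = 0.025; adjusted p = 0.97 with an estimated correlation), but only COX6C and NDUFB8 of 33 rose and none passed adjusted over the list alone. Both calls held only when 2D replicate 3 was the library left out (adjusted p of COX6C 0.00023 to 0.087 over the 6 fits). COX6C, a subunit of complex IV, rose from 813 ± 337 to 1637 ± 111, and NDUFB8 is uncertain, with 53.8% of its windows shared. This call was lost without 2D replicate 2 or 3D replicate 2 (adjusted p = 0.20 and 0.23; range over 18 alternatives 0.0037 to 0.23). Fry did not call the nuclear list either (adjusted p = 0.32). Members past the threshold numbered 11 without 2D replicate 3, 1 without 2D replicate 2 and 0 in each of the other fits with a library left out. Of 10 genes of PGC1-alpha and mitochondrial biogenesis, 0 rose and NRF1 fell, also adjusted over the list alone (camera, adjusted p = 0.94), a call of NRF1 lost without 2D replicate 1, 2D replicate 2, 3D replicate 1 or 3D replicate 3 (adjusted p of 0.0021 to 0.067 over the 6 fits). Without 2D replicate 3, 3 of these 10 genes were higher and 2 lower.

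Genes of the ATF4 and amino acid response fell, and the size of the fall depended on 2D replicate 3. As a list they did not pass fry (adjusted p = 0.15). Of 31 genes, 15 fell and none rose (23 fell adjusted over the list alone), with a median log2 change of -1.66 (camera, adjusted p = 1.3e-08; adjusted p = 0.97 with an estimated correlation). ATF3, a stress-induced transcription factor, fell from 2447 ± 247 to 292 ± 34.9 (log2 -3.06, SE 0.18, adjusted p = 0.00011). SLC7A5 and SLC3A2, the chains of a large neutral amino acid transporter, fell from 46586 ± 15912 to 6863 ± 991 and from 19532 ± 7923 to 3665 ± 636. VLDLR, a lipoprotein receptor, fell from 637 ± 318 to 94.4 ± 21.6. The mean level of the list was 1.95 and 1.82 in 2D replicates 1 and 2, -0.70 in 2D replicate 3 and -1.12 to -0.92 in 3D. Members that fell numbered 30 without 2D replicate 3, but 6, 5, 5, 7 and 4 without 2D replicate 1, 2D replicate 2, 3D replicate 1, 3D replicate 2 and 3D replicate 3. Of 20 genes of ER stress, 5 fell and none rose, also adjusted over the list alone (camera, adjusted p = 0.16), among them XBP1, a transcription factor of the unfolded protein response, from 9579.5 ± 5072 to 1969 ± 153. Of 15 heat shock genes only the co-chaperone CHORDC1 passed, falling from 686 ± 265 to 126 ± 71.7 (camera for the list, adjusted p = 0.93). Without 2D replicate 3, 6 heat shock genes were higher and 2 lower, and 3 ER stress genes were higher and 8 lower. ER stress genes that fell numbered 3 without 3D replicate 2 and 1 without any of the other 4 libraries, with 0 higher in each.

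Targets of hypoxia-inducible factor (HIF) shifted upward relative to other genes, but did not pass the test of moving in 1 direction on balance (fry, adjusted p = 0.066). Of 27 tested, 8 rose and 1 fell, in all genes and adjusted over the list alone, with a median log2 change of 0.60 (camera, adjusted p = 0.0012; adjusted p = 0.97 with an estimated correlation). The lipase inhibitor ANGPTL4 rose from 50.7 ± 18.2 to 449.5 ± 11.7, EGLN3, a HIF prolyl hydroxylase, from 72.9 ± 60.7 to 669 ± 111, and PFKFB4, a regulator of glycolysis, from 103 ± 89.9 to 924 ± 431. BHLHE40, a transcriptional repressor, rose by 1.14 on the log2 scale. The hydroxylase EGLN1 fell from 2208 ± 437 to 1328 ± 129. The call of EGLN1 held only when 2D replicate 3 was the library left out (adjusted p of 0.0018 to 0.12 over the 6 fits). The list's mean level in 3D replicate 2 was 0.02, against 0.75 and 0.56 in the other 3D libraries. Without 2D replicate 2, 3D replicate 1 or 3D replicate 3 only 5 members rose, and without 2D replicate 3 12 rose and 4 fell. Glycolysis genes also passed (median log2 0.54; camera, adjusted p = 0.0042; adjusted p = 0.97 with an estimated correlation). Fry did not call the glycolysis list (adjusted p = 0.23). There 4 of 17 rose, also adjusted over the list alone: ALDOC from 668 ± 687 to 3163 ± 899, PGK1 from 14803 ± 5462 to 28009 ± 2513, HK1 from 1422 ± 792 to 2848 ± 270.3, and ALDOA, of which 48.7% of windows are shared. None of the 17 passed without 2D replicate 1, 2D replicate 2, 3D replicate 1 or 3D replicate 3, 3 passed without 3D replicate 2 (PGK1 and HK1 not among them), and 14 passed without 2D replicate 3, in which the list's mean level of 0.23 lay within the 3D range of 0.16 to 0.47.

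Targets of the coactivators YAP and TAZ fell. Of 23 genes, 14 fell and none rose (16 fell and 1 rose adjusted over the list alone), with a median log2 change of -1.27 (camera, adjusted p = 7.6e-07; adjusted p = 0.19 with an estimated correlation). AMOTL2, a junctional regulator of YAP, fell from 5761 ± 1024 to 619 ± 139 (log2 -3.22, SE 0.22, adjusted p = 0.00029), the Hippo kinase LATS2 from 1378 ± 161 to 281 ± 26.4, CRIM1 from 5699 ± 368 to 1334 ± 216, and TGFB2, with 26.0% of windows shared, from 604 ± 93.7 to 57.8 ± 22.5. Actin and SRF targets fell likewise, 7 of 19 (8 adjusted over the list alone), with a median of -0.51 (camera, adjusted p = 0.0094; adjusted p = 0.97 with an estimated correlation). LIMA1, an actin-bundling protein, fell from 10193 ± 338 to 2336 ± 372 and the myosin light chain MYL9 from 2967 ± 445 to 1308 ± 312. SRF itself fell from 1733 ± 156 to 994 ± 44.6, a call lost without 2D replicate 1 or 3D replicate 1 (adjusted p of 0.0014 to 0.057 over the 6 fits). The set call was lost without 2D replicate 3 (adjusted p = 0.055; range over 18 alternatives 0.00091 to 0.055). There 10 members fell and 2 rose, and 4, 4, 2 and 3 fell without 2D replicate 1, 2D replicate 2, 3D replicate 1 and 3D replicate 3. Among 28 integrin and focal adhesion genes, 4 rose and 6 fell, also adjusted over the list alone (camera, adjusted p = 0.36). ITGA10 rose as given above, while CAV1, the main caveolar coat protein, fell from 1651 ± 80.2 to 146 ± 38.2 and the adaptor PARVA from 6933 ± 368 to 2113 ± 421. In the integrin list 7 genes were higher and 9 lower without 2D replicate 3, and 4 were lower without 2D replicate 2 or 3D replicate 3.

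Immediate early genes passed the set test in the downward direction, with 6 of 24 lower and 1 higher, also adjusted over the list alone (median log2 -0.38; camera, adjusted p = 0.044; adjusted p = 0.97 with an estimated correlation). ATF3 is among them. Fry did not call this list (adjusted p = 0.25). NR4A3, an orphan nuclear receptor, fell from 1166 ± 333 to 126 ± 9.22, JUND, an AP-1 subunit, from 8855 ± 1012 to 4312 ± 199.8, and DUSP1, a MAP kinase phosphatase, from 19746 ± 14177 to 2108 ± 1444. IER3 rose from 5.49 ± 2.31 to 28.1 ± 11.1, with 22.5% of its windows shared, a call lost without 2D replicate 1 or any 3D library (adjusted p of 0.0082 to 0.083 over the 6 fits). The list's mean level was 1.52 in 2D replicate 3 against -0.34 and -0.25 in the other 2D libraries. The set call was lost without 2D replicate 3, where the median turned to 0.31 (adjusted p = 0.76) with 4 members higher and 8 lower, and without 3D replicate 1 (adjusted p = 0.099); over 18 alternatives adjusted p ran from 0.00090 to 0.76. Of 18 genes of MAPK output, 4 rose and 2 fell, also adjusted over the list alone (camera, adjusted p = 0.68). The phosphatase DUSP4 rose from 372 ± 163 to 1971 ± 763 and DUSP5 fell from 628 ± 415 to 103 ± 18.5. Genes of MAPK output that rose numbered 1 without 2D replicate 1, 3D replicate 1 or 3D replicate 3, and 2 without 2D replicate 2 or 3D replicate 2.

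Collagen and matrix genes shifted upward relative to other genes, but did not pass the test of moving in 1 direction on balance (fry, adjusted p = 0.20). There were 9 of 24 higher and 2 lower (12 and 2 adjusted over the list alone) and a median log2 change of 0.77 (camera, adjusted p = 0.035; adjusted p = 0.97 with an estimated correlation). Fibronectin, encoded by FN1, rose from 696 ± 305 to 7952 ± 3589 (log2 3.51, SE 0.37, adjusted p = 0.00083), COL3A1 from 899.6 ± 736 to 5705 ± 1924, COL5A1 from 2807 ± 2102 to 10090.2 ± 1309, and the laminin chain LAMA4 from 17.6 ± 8.85 to 175 ± 116. COL12A1 fell from 8227 ± 2479 to 2719 ± 459.6 and the microfibril protein FBN1 from 6080.4 ± 1316 to 2447 ± 238. The set call was lost without 2D replicate 1 (adjusted p = 0.096) and with equal library totals (adjusted p = 0.056; range over 18 alternatives 0.00065 to 0.096). Members that rose numbered 4 without 2D replicate 1, 2D replicate 2, 3D replicate 1 or 3D replicate 3, and 14 without 2D replicate 3. Of 15 EMT factors and mesenchymal markers, 3 rose and 2 fell (4 and 2 adjusted over the list alone; camera, adjusted p = 0.96). MMP2, a gelatinase, rose from 185 ± 48.9 to 4302 ± 2817 and the repressor ZEB2 fell from 308 ± 99.5 to 58.9 ± 15.2, and 6 of these 15 were higher and 3 lower without 2D replicate 3.

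Melanoma state and lineage genes moved in both directions. Several pigment cell genes lay near the floor in both cultures (MLANA 10.2 in 2D and 8.26 in 3D, S100B 5.13 and 0.323). KRT8 was abundant (24771 and 24927), and the identity of the cells rests on the labels, as the closing section describes. MITF (ENSG00000187098), the regulator of the melanocytic programme, fell from 1131 ± 215 to 288 ± 19.02 (log2 -1.95, SE 0.20, adjusted p = 0.00077). AXL (ENSG00000167601), a receptor kinase of undifferentiated melanoma, fell too, from 2696 ± 263 to 1215 ± 386 (log2 -1.19, SE 0.23, adjusted p = 0.0093), a call lost without 3D replicate 3 (adjusted p of 0.0029 to 0.052 over the 6 fits). SOX10, a neural crest factor, was too low to test, with 16.1 ± 18.2 in 2D, of which 2D replicate 3 had 37.0, and 2.54 ± 2.43 in 3D. Of 10 melanocytic differentiation genes 1 rose and 4 fell (2 and 5 adjusted over the list alone). This list did not pass camera (adjusted p = 0.45) but passed fry (adjusted p = 0.034). DCT, a melanin synthesis enzyme, had 70.01 ± 42.4 in 2D and 2 reads in all of 3D, a ratio of 108 (interval 29.4 to 895) that was 71.3 (19.2 to 598) without 2D replicate 3. Both reads were in 3D replicate 1, and without it DCT was at least 46.6-fold lower. Of 20 genes of undifferentiated melanoma 2 rose and 8 fell, also adjusted over the list alone (camera, adjusted p = 0.33), with the YAP partner TEAD1 falling from 18461 ± 4077 to 3610.1 ± 381 and TEAD4 from 1397 ± 56.7 to 611 ± 80.6. Of 11 genes of neural crest-like melanoma 2 rose and 3 fell (2 and 4 adjusted over the list alone; camera, adjusted p = 0.72), and the list's median of -0.60 and mean of 0.35 differed in sign. SOX9 rose from 3.01 ± 3.09 to 60.5 ± 19.4 and MSX1 fell from 704 ± 86.2 to 309 ± 13.5. Melanocytic genes that fell numbered 5 without 2D replicate 3 and 2 without any other library. Undifferentiated genes that fell numbered 4 without 3D replicate 1 and 3 without 3D replicate 3, and 5 rose without 2D replicate 3.

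Markers of other cell types gave no list past the set test. Of 12 epithelial markers 1 rose and 4 fell, also adjusted over the list alone (camera, adjusted p = 0.33). The tight junction protein CLDN4 rose from 391 ± 105 to 2309.7 ± 164, while E-cadherin, encoded by CDH1, fell from 92.3 ± 20.2 to 5.62 ± 2.74. Of 7 keratinocyte markers PERP rose and KRT17 and LAMB3 fell, also adjusted over the list alone (camera, adjusted p = 0.75). With a library left out, these calls held only where that library was 2D replicate 3. Of 6 fibroblast markers COL3A1 rose and MFAP5 fell, from 6836 ± 1046 to 1664 ± 398 (2 and 1 adjusted over the list alone; camera, adjusted p = 0.63). Of 7 endothelial markers PECAM1 rose and ESAM fell, also adjusted over the list alone (camera, adjusted p = 0.87), ESAM losing its call without 2D replicate 1, 2D replicate 2, 3D replicate 1 or 3D replicate 3 (adjusted p of 0.034 to 0.15 over the 6 fits). Of 7 Schwann and glial markers 0 rose and 2 fell, also adjusted over the list alone (camera, adjusted p = 0.75), with myelin basic protein (MBP) falling from 493 ± 32.6 to 226 ± 25.1. Of 8 neuronal markers 2 rose and 2 fell (3 and 2 adjusted over the list alone; camera, adjusted p = 0.94), with MAP2 falling from 96.3 ± 21.8 to 18.4 ± 2.93. Leukocyte markers were too low to test as a list, with 10 measured. Over the 37 lists that did not pass, 76 memberships were higher and 98 lower in 3D; without 2D replicate 3 these were 149 and 155, and they fell to 29 and 50 without 3D replicate 3, 33 and 50 without 3D replicate 1, 38 and 56 without 2D replicate 1, and 36 and 57 without 2D replicate 2.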

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

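The fit without 2D replicate 3 and 3D replicate 2 was chosen after the data were seen; it called 9041 genes (4436 higher, 4605 lower). The other alternatives were fixed before. With 1 library left out, the count of genes ran from 1190 to 7111 (higher 534 to 3526, lower 656 to 3585) and the count of lists from 10 to 12. Fewer libraries lower the power, and 2D replicate 3 widens the spread in 2D, but the cause was not tested further. An adjusted p under 0.01 left 1121 genes (541 higher, 580 lower), and a log2 change of at least 1 left 1003 lower. DESeq2 called 4724 genes, 3748 of them among the 3766, and edgeR shared 3460. Without a filter 18 lists passed, including the 11. With an estimated correlation 0 passed, against 11 with the preset one and 7 by fry, which shared 3 (G2 and M phase, YAP and TAZ targets, actin and SRF targets). Fry also called fatty acid synthesis, drug efflux transporters, antigen presentation and melanocytic differentiation, which camera did not. The YAP and TAZ list lost its camera call although its estimated correlation of -0.0087 was under the preset 0.01. The loss of calls with an estimated correlation therefore does not show that co-movement of members removed them. Nuclear OXPHOS lost its call with edgeR and DESeq2 (adjusted p = 0.077 and 0.063; range over 18 alternatives 0.0037 to 0.23).

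With the replicate number as a block, 3222 genes passed (2971 shared) and the same 11 lists. Deviations from the culture means correlated between same-numbered libraries at -0.0840, -0.139 and 0.0447. Not every library correlated best with its own number, so these values show no pairing by number. They cannot exclude a pairing, since 2D replicate 3 and 3D replicate 2, which stand apart, weigh heavily in these deviations. Of 184 named genes tested, 169 passed and 119 of these kept the call with each library left out; none of the 169 changed sign. The fold of 30 of them moved by over 1.5 times in at least 1 of these fits, of 23 without 2D replicate 3, all to a larger change. With a library left out, the log2 change of NGFR ran from -0.0097 (without 2D replicate 1) to 1.06 and that of ALDH1A3 from -0.057 (without 3D replicate 1) to 0.45; neither passed in any of these fits, and the cause was not tested. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. With the real split counted, 1 split gave as many as its 3766 genes and 5 splits as many as its 11 lists. The highest other split gave 0 genes and 14 lists. By the number of lists called, the real split did not stand apart. Every other split mixes the cultures unequally, so part of their difference remains between its sides and the rest widens the spread within them. The counts of the other splits therefore do not show how many genes or lists pass where no difference exists. A comparison with a table of the authors' own was not run. At this depth and spread, 15% of simulated changes of 1 on the log2 scale were recovered. The simulation changed far fewer genes than the 3766 called here, and the adjusted threshold depends on that number. Its share recovered therefore does not carry over to these data. Of the 3766 genes, 2627 had a change of at least 1 on the log2 scale, so smaller changes were called too. The share of smaller changes missed here was not tested.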

Other observations

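Signalling lists not described so far held strong changes in both directions. Among 14 Notch pathway genes, NOTCH3 rose from 1025 ± 946 to 7159.5 ± 293 and its target HEY1 from 77.6 ± 12.4 to 469.8 ± 107, while NOTCH2 fell from 5708 ± 1246 to 2866 ± 187; 2 rose and 3 fell in all (camera, adjusted p = 0.93). Of 17 TGF-beta targets 4 rose and 4 fell (camera, adjusted p = 0.94), with the inhibitors of differentiation ID1 and ID2 falling from 2389 ± 837 to 373 ± 262 and from 337 ± 214 to 19.8 ± 2.18. Of 20 NF-kB targets and cytokines 4 rose and 4 fell (camera, adjusted p = 0.94): PTGS2, which makes prostaglandins, rose from 12.9 ± 3.14 to 137 ± 34.7 and CSF1 fell from 257 ± 63.8 to 65.9 ± 18.9. Of 21 p53 targets 3 rose and 3 fell (camera, adjusted p = 0.96), and of 29 interferon-stimulated genes 5 rose and 5 fell (camera, adjusted p = 0.98), with MX1 falling from 219 ± 45.6 to 77.3 ± 12.3. Of 14 Wnt targets 2 rose and 1 fell (camera, adjusted p = 0.75) and of 9 Hedgehog genes 2 rose and 2 fell (camera, adjusted p = 0.75), with GLI2 falling from 725 ± 134 to 325 ± 63.8. Without 2D replicate 3, 12 interferon-stimulated genes were higher and 5 lower, and without 2D replicate 1, 2D replicate 2, 3D replicate 1 or 3D replicate 3 these were 0 and 2. Likewise 7 p53 targets and 7 NF-kB targets were lower and 4 Wnt targets higher without 2D replicate 3, and without 3D replicate 2, 7 TGF-beta targets were lower. Without 3D replicate 3, 2 NF-kB targets were higher and 2 lower, 0 Hedgehog genes were higher, and 0 Notch genes were lower. The call of NOTCH2 was lost without 3D replicate 3 (adjusted p of 0.0013 to 0.055 over the 6 fits). The median and mean of the list differed in sign for Notch, TGF-beta and p53, and also for the autophagy, heat shock, reference, EMT and endothelial lists. Adjusted over the list alone, the counts were 5 and 5 for TGF-beta, 4 and 5 for NF-kB, 3 and 4 for p53 and 6 and 5 for interferon, and as given for the rest.

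Of 21 NRF2 and oxidative stress genes 3 rose and 1 fell (1 and 1 adjusted over the list alone; camera, adjusted p = 0.75), led by AKR1C1 from 34.8 ± 27.8 to 1221 ± 915, with 22.2% of windows shared. Of 10 drug efflux transporters 2 rose and 1 fell (3 and 1 adjusted over the list alone), with ABCC2 rising from 972 ± 449 to 2639 ± 108. The transporter list passed fry (adjusted p = 0.019) but not camera (adjusted p = 0.33). Among transporters, 1 was higher and 0 lower without 2D replicate 1, 2D replicate 2 or 3D replicate 1, and 4 were higher and 2 lower without 2D replicate 3. Of 25 autophagy and lysosome genes 2 rose and 3 fell (0 and 2 adjusted over the list alone; camera, adjusted p = 0.91), with the glycoprotein GPNMB falling from 1996 ± 541 to 342 ± 165. Metallothioneins gave 1 of 5 higher (2 adjusted over the list alone; camera, adjusted p = 0.51), ribosomal proteins 1 of 38 higher, also adjusted over the list alone (camera, adjusted p = 0.33), and ribosome biogenesis and MYC targets 2 of 25 lower (1 adjusted over the list alone; camera, adjusted p = 0.46). Without 2D replicate 3, 14 ribosomal protein genes were lower and 1 higher, 7 ribosome biogenesis genes were lower, 8 NRF2 genes were higher and 3 lower, and 6 autophagy genes were higher and 6 lower. Without any other library 1 NRF2 gene and 0 autophagy genes were higher, and 0 metallothioneins, against 3 without 2D replicate 3. Reference genes gave 2 of 15 higher and 1 lower, also adjusted over the list alone (camera, adjusted p = 0.96), and 5 higher and 2 lower without 2D replicate 3. Without 2D replicate 1, 2D replicate 2 or 3D replicate 1, 0 reference genes were higher. Of 10 antigen presentation genes 2 rose and 2 fell, also adjusted over the list alone (camera, adjusted p = 0.87), and the list passed fry (adjusted p = 0.018). Of these genes, 0 were higher and 2 lower without 2D replicate 1, 2D replicate 2 or 3D replicate 1, and 3 were higher and 3 lower without 2D replicate 3. Of 153 protein-coding genes annotated between 29000000 and 33000000 of chromosome 6, which holds the major histocompatibility complex, 26 were analysed here and 11 of these had a mean of at least 10, against 681 analysed of 891 and 548 of these on the rest of the chromosome; low expression was not separated from uncounted reads. Of 858 antisense genes 189 were higher and 22 lower, and of 653 lincRNAs 144 were higher and 35 lower, without strand information, while of 461 processed pseudogenes 15 were higher and 16 lower.

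In the paragraphs that follow, the tests were chosen after the result was seen, except that of shared sequence windows, and genes named there outside the naming rule were chosen after their values were seen. The place of 2D replicate 3 between the cultures was set against a mixture and a wrong label; no biological explanation was tested. A mixture with 3D cells or RNA would put all genes at a single position between 3D (0) and the other 2D libraries (1). The median position was 0.296 (bootstrap interval 0.242 to 0.348) for 457 genes higher in 2D and 0.793 (0.772 to 0.818) for 1097 genes higher in 3D, a difference of 0.497, which argues against a mixture as the whole cause. Bootstrap intervals here and below resampled genes, not libraries, so they do not measure the spread between libraries. Of 224 genes over 16-fold apart between the cultures, 62.5% lay nearer to the other 2D libraries, which argues against a 3D library labelled as 2D. Of 11094 abundant genes, 71 in this library lay over 2-fold above all others and 31 under 0.5 of all others, against 58 and 68 in 3D replicate 2, so standing apart in this way is not particular to it; FOS (29289), EGR1 (16787) and CCN1 (18821) stood out, while ASNS (12.3) and CHAC1 (48.3) lay near the 3D libraries, far below the other 2D libraries.

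The rise of mitochondrially encoded transcripts may be technical or biological. Over the scalings tried the lowest median log2 change was 2.52. Between them the median of all tested genes moved only from -0.02 to 0.11, so they could not remove a change of this size. They show only that the choice among these scalings does not account for the rise. A rise of the respiratory chain from both genomes alike would give the nuclear genes a median near 2.52 on the log2 scale. A lower cut-off of 1.26 was set after the result was seen. The nuclear median was 0.289 (bootstrap interval over genes 0.199 to 0.443) and ran from 0.16 to 0.42 over 18 alternatives, which argues against a rise from both genomes alike. Carry-over of RNA without a poly(A) tail was held to the same cut-off of 1.26. The 20 such RNAs tested, 16 of them replication-dependent histone genes, had a median of 0.566 (bootstrap interval over genes -0.103 to 1.03, under 1.26). Carry-over cannot be told apart, as the RNAs went both ways (RN7SL2 -4.54, SNORA73B 2.66) with an SD of 1.76 and histone transcripts vary with the cell cycle. The comparison bears on mitochondrial transcripts only so far as they lack such a tail, which was not examined here. A change of mitochondrial transcript levels in sphere culture also stays open and untested.

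Several pigment cell genes lay near the floor in libraries labelled as a melanoma line while keratins were abundant, but PMEL (434 and 1071 in 2D and 3D) and MITF (1131 and 288) did not. MLANA averaged 10.2 and 8.26 in 2D and 3D, S100B 5.13 and 0.323, TYR 14.8 and 0.323, and TYRP1 12.5 and 1.94. By contrast, KRT8 averaged 24771 and 24927, KRT18 11234 and 10689, and KRT7 11323 and 906. FOLR1, the folate receptor, was the gene of rank 3 by mean. CPS1 (62187 and 29095) and CGA (33253 and 32523) had ranks 15 and 33. Reads shared between genes do not account for it, as at most 4.27% of the windows of 6 pigment cell genes occur elsewhere. An undifferentiated state of the line stays open: 95% of 20 measured genes of the undifferentiated list had a mean of at least 100, but so did 69.2% of 13 epithelial genes, against 27.8% of 18 melanocytic ones. Cells other than the labelled line cannot be told apart from it either, since no genotype was analysed here and SOX10, which reached at most 37.0, does not decide it.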
